A study of Mus musculus with 2 samples.

How the data were processed

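Foxp4-bound DNA was isolated from sonicated nuclei of differentiating stromal vascular fraction cells with a Foxp4 antibody, per the labels' protocols, and input DNA was sequenced beside it. Per the labels, cells from C57BL/6 mice were grown for 3 days in medium with 20% serum and then induced for 48 h in medium with 10% serum, 5 µg/ml insulin, 0.5 mM isobutylmethylxanthine, 1 µM dexamethasone, 50 nM T3 and 5 µM troglitazone. There were 2 samples, 1 ChIP library and 1 input library, so no replicate error exists. The input library was not analysed here.

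The deposited values were a list of peaks with their mm10 positions, annotated with HOMER's annotatePeaks.pl from a narrowPeak file, per the file headers. Bowtie2, Picard, SAMtools, MACS2 and deepTools 3.3.0 are named in the submitters' processing notes without their roles or settings. Each peak has a whole-number score, the only measure of strength in the file the authors deposited. It is taken to be 10 times -log10 of the caller's q, on which the lowest score of 13 would be a q of 0.050, but the sources used here do not state this. A score of this kind mixes enrichment with read depth and peak width, so it was used only to rank, filter and describe peaks within this list. Pileup, fold enrichment, summit and read depth were not used here. How the input entered the peak calls, and how reads with several alignments were treated, is not given in the sources used here. Both could change which repeats and multicopy loci appear as peaks.

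All 3317 peaks were kept, and 1 line with no peak was left out. Distances to start sites, nearest genes, annotation classes and repeat annotations are those of the file, and a peak's position is its midpoint. Gene names, types and positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly behind mm10, in which 2459 of the 2462 nearest genes were found by their gene number. As a check of the build, the start site implied by each peak's distance lay inside the named gene, or within 2 bp of it, for 99.1% of 3309 peaks. It lay within 2 bp of an end of that gene for 1782 of these peaks (53.9%). The table has no strand, sequence or chromosome lengths. For that reason the planned random placements around start sites were replaced by placements around either end of the 26215 genes with a curated transcript. Densities per Mb use the span from the first to the last annotated gene. The planned scan of 18 sequence motifs was not run. The score stood in for the planned fold enrichment, and a score of at least 30 for a q under 0.001.

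The 19 gene lists (633 symbols, of which 1 was not matched) were fixed before the data were examined, as were the promoter window of 3 kb, the list tests and the rule for named genes. That rule named the 10 highest-scoring peaks, up to 4 members per list with the highest scores among promoter peaks (or among nearest genes if there were none), and in every case Foxp1, Foxp2, Foxp4, Ucp1, Ppargc1a, Prdm16, Cebpb, Pparg, Ebf2 and Pdgfra. Members named beyond it (Zbtb16, Ror2 in its list, Nfib, Egr2, Klf9 in the adipogenic list, Wt1 and Upk1b) and genes with many peaks were chosen after their values were seen. Some results are not reported here. Each list was tested with Fisher's exact test, two-sided, against the other protein-coding genes among 21883, with odds ratios and exact conditional intervals and Benjamini-Hochberg adjustment over the 19 lists, separately for nearest start sites and for the 3 kb window. Within 3 kb, too, a peak counted only for the gene that the file names as nearest. A list member with a peak inside its window that was closer to another gene's start site was not counted. Genes that lie far from their neighbours collect more peaks by chance. Each nearest count was therefore also set against 10000 random lists matched on decile of gene territory, the gene body and the gap up to the midpoint to the neighbouring gene bodies (start sites had been planned). Genes are features of 1 library, so these p-values describe how peaks fall over genes in this library and not variation between cultures.

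Shares have exact (Clopper-Pearson) 95% binomial intervals and densities exact Poisson intervals. Median scores were compared with two-sided permutation tests of 100000 permutations and intervals from 2000 bootstrap draws, and 6 of these comparisons were adjusted as a family. The comparisons of chromosome X, of other simple repeats with peaks that had none, within quartiles of width and under the alternatives were outside it and not adjusted. The comparisons of repeats, rings around start sites, gene ends, X with autosomes, neighbouring peaks and pairs of lists were added after the data were seen, as were the assignment of peaks to gene bodies with 20 kb on each side and the test of glucocorticoid-induced genes without shared members. The pairs of lists had been picked by their counts, so their tests are not given. Alternatives covered the promoter window, score limits, distance limits, the background genes and simple-repeat peaks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

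The procedures were tested on simulated data. Over 100 runs on 21883 genes, the number of genes with a peak within 3 kb was drawn at random. To these were added members of a chosen list, 6 times the expected number, on top of those already drawn. The chosen list was recovered in 69% of runs, and 0.177% of the other lists were called. The larger number of genes with a peak by nearest start site was not simulated. In 20 runs of the placement test on 26215 genes, with fewer placements than in the analysis, 100% of runs with 10% of peaks moved to gene starts and 5% of uniform runs were called. The score test was run 50 times on smaller groups of scores drawn from the 3317 peaks, with fewer permutations than in the analysis. In these, 100% of runs with 2-fold scores and 6% of runs with equal scores were called. Differences smaller than 2-fold were not simulated, so these runs give no power for them.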

Results

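Foxp4 is a transcription factor of the forkhead family. Its binding sites were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in cells at an early stage of becoming beige adipocytes, the fat cells that can acquire heat-producing capacity inside white fat. The cells were the stromal vascular fraction of inguinal white adipose tissue of C57BL/6 mice, a mixture of progenitors, fibroblasts and other non-adipocyte cells, grown to confluence and induced to differentiate for 2 days. The series held 1 Foxp4 ChIP library and 1 input DNA library. The values analysed here were the authors' peaks of the ChIP library, so no value has a replicate error and no groups of samples could be compared. Read depth is unknown, and the intervals below cover counting error over the peaks or genes of this 1 library.

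The deposited list held 3317 peaks on mm10 with a median width of 393 bp (quartiles 333 to 487), covering 1449 kb in all. Each peak carries a score given by the authors' processing, whose median was 65 (quartiles 41 to 104) and whose range was 13 to 2569. The highest score lay in intron 1 of Ror2, a Wnt5a receptor (chromosome 13, 53275734 to 53276533). A score of 1519 was reached by a peak in intron 13 of Col3a1, which encodes a fibrillar collagen (chromosome 1, 45329203 to 45330077), and by an intergenic peak nearest to Ptger2, a prostaglandin E2 receptor (chromosome 14, 45051478 to 45052379). The other peaks among the 10 highest were nearest to 1700116B05Rik (score 1370), Tapt1 (1350), Kcnh1 (1145), Mir7007 (1110), Bloc1s5 (1098), B230354K17Rik (1081) and Dtwd1 (1037). Of these 10, the peak at B230354K17Rik was the 1 annotated as a promoter, 106 bp from the start site.

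Most sites were distal. Of the 3317 peaks, 1674 were intergenic (50.5%, exact 95% binomial interval 48.8 to 52.2), 1271 lay in introns (38.3%, 36.7 to 40.0) and 278 were annotated as promoters (8.38%, 7.46 to 9.38). The remaining classes were small, with 33 peaks at transcription ends, 20 in 5' UTRs, 17 in exons, 12 in 3' UTRs and 12 in non-coding transcripts. Within 3 kb of a start site lay 547 peaks (16.5%, 15.2 to 17.8), at 517 genes, of which 458 were protein-coding. A further 1168 peaks (35.2%) lay 10 to 50 kb away and 706 (21.3%) more than 100 kb away.

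Peaks were nevertheless more frequent at start sites than beside them. There were 364 peaks within 1 kb of a start site and 104 in the ring from 1 to 2 kb, a ratio of 3.5 (95% interval 2.81 to 4.40, exact binomial test, two-sided, p = 7.47e-35). Against the ring from 3 to 4 kb the ratio was 6.17 (4.68 to 8.27). Both ratios take each distance from the nearest start site to hold equal sequence. Where start sites lie close together less sequence is left at larger distances, which by itself raises the ratios, by an amount not measured here. The binomial test also treats peaks as independent, including those that lie close together. Within 3 kb of either end of a gene lay 19.4% of the peaks, against 9.50% ± 0.513 (SD over 1000 random placements on the same chromosomes, two-sided permutation p = 0.001, the smallest that 1000 placements can give). Gene bodies held 46.7% of the peaks against 42.7% ± 0.848 (permutation p = 0.001). Assembly gaps, which the plan excluded, were kept in these placements, and peaks that lie close together were placed independently. The small excess in gene bodies can therefore not be separated from the way the placements were drawn. Peaks within 3 kb of a start site had a median score of 62 and the others one of 65, a difference of -3 (bootstrap interval -9 to 4) that did not pass a two-sided permutation test (p = 0.43). In 5 groups of 663 or 664 peaks from the highest to the lowest score, the number within 3 kb was 126, 86, 92, 124 and 119, with no steady trend. It was 1 of the top 10 peaks, 15 of the top 50 (30%, 17.9 to 44.6) and 25 of the top 100 (25%, 16.9 to 34.7), which was not tested. The ring and gene-end comparisons were chosen after the peak positions were seen.

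**Figure D1:**
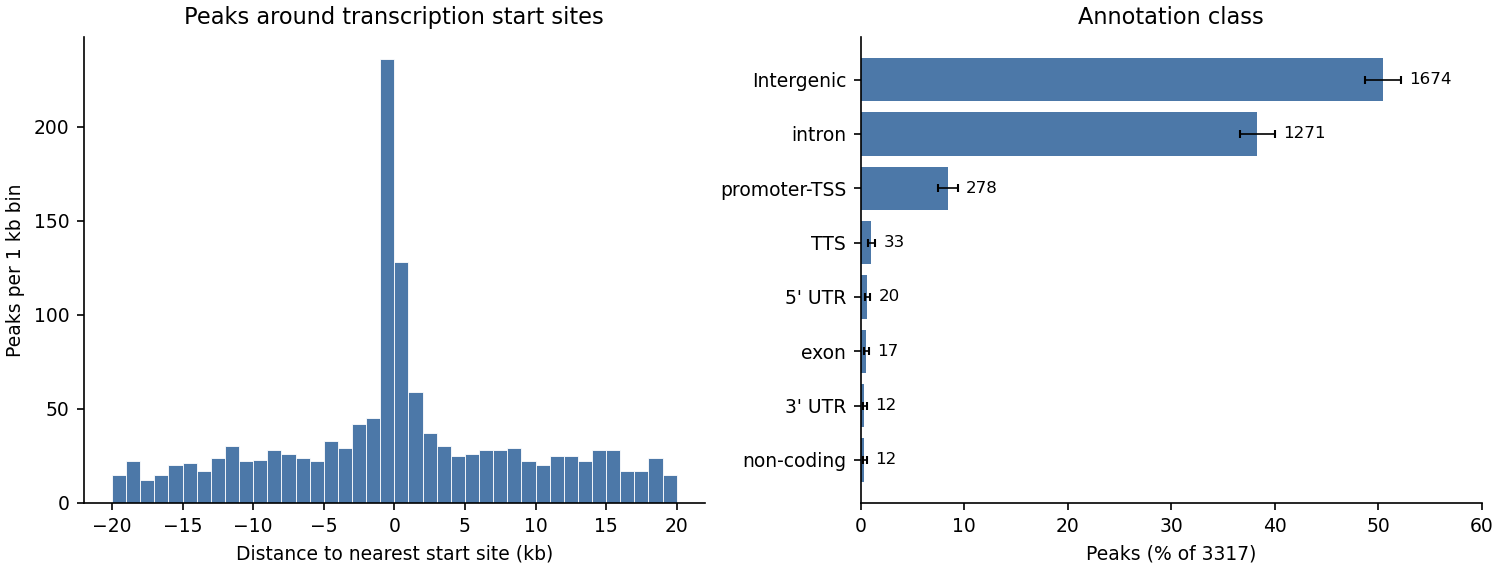
Left, number of peaks in 1 kb bins of the signed distance from the nearest start site (kb), with 236 peaks in the bin just upstream of the start site and 128 in the bin just downstream. Right, share of the 3317 peaks in each annotation class (%), with exact 95% binomial intervals and the number of peaks beside each bar; intergenic and intron peaks are the longest bars.

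A set of high-scoring sites lay on short tandem repeats made of a run of T followed by G. Repeats were annotated at 772 peaks (23.3%, 21.8 to 24.8), of which 285 were simple repeats, 123 L1 elements and 74 elements of the Alu family, which in mouse are the B1 elements. Of the 285 simple-repeat peaks, 212 (74.4%, 68.9 to 79.4) had a unit of 2 to 5 T and 1 G on 1 of the strands, called TnG here, and these were 6.39% of all peaks (5.58 to 7.28). They comprised 83 peaks on (TTG)n with a median score of 119, 93 on (TTTG)n with 94, 9 on (TTTTG)n with 81 and 27 on (TTTTTG)n with 93. Another 44 peaks lay on (TG)n, with a median of 84.5.

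TnG repeats held 4 of the 10 highest peaks, those at Ror2, Ptger2, Col3a1 and 1700116B05Rik, 12 of the top 50 and 22 of the top 100. They made up 14.3% (11.8 to 17.2) of the 663 highest-scoring peaks and 2.26% (1.27 to 3.70) of the 664 lowest. Their median score was 101.5 against 62 for the other 3105 peaks, a difference of 39.5 (bootstrap interval 28.0 to 59). Because the group was formed from the highest peaks, a test of this difference on all peaks restates what was seen. Without the 10 highest peaks the difference was 38 (24.0 to 57) and passed a two-sided permutation test (p = 1e-05, not adjusted, the smallest that 100000 permutations can give). Against the 73 peaks on other simple repeats the difference was 15.5 (-4 to 39.5) and did not pass (permutation p = 0.24, adjusted p = 0.48 over 6 score comparisons). Those 73 peaks, of which 44 were (TG)n, also scored above the 3032 peaks with no simple repeat, by 24 (9 to 41, permutation p = 0.00056, not adjusted). The (TG)n peaks alone did so by 22.5 (8.5 to 39, adjusted permutation p = 0.026). For the other 29 the difference was 25 with an interval that includes 0 (-8 to 59, permutation p = 0.019, not adjusted). For the 278 peaks annotated as promoters the detailed annotation repeats that class, so repeats at promoters are not seen here, and how often these repeats occur in the genome was not compared here. The repeat groups were formed after the annotations of the highest peaks were seen, and the tests without the 10 highest peaks and against peaks with no simple repeat were added after the other results.

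**Figure D2:**
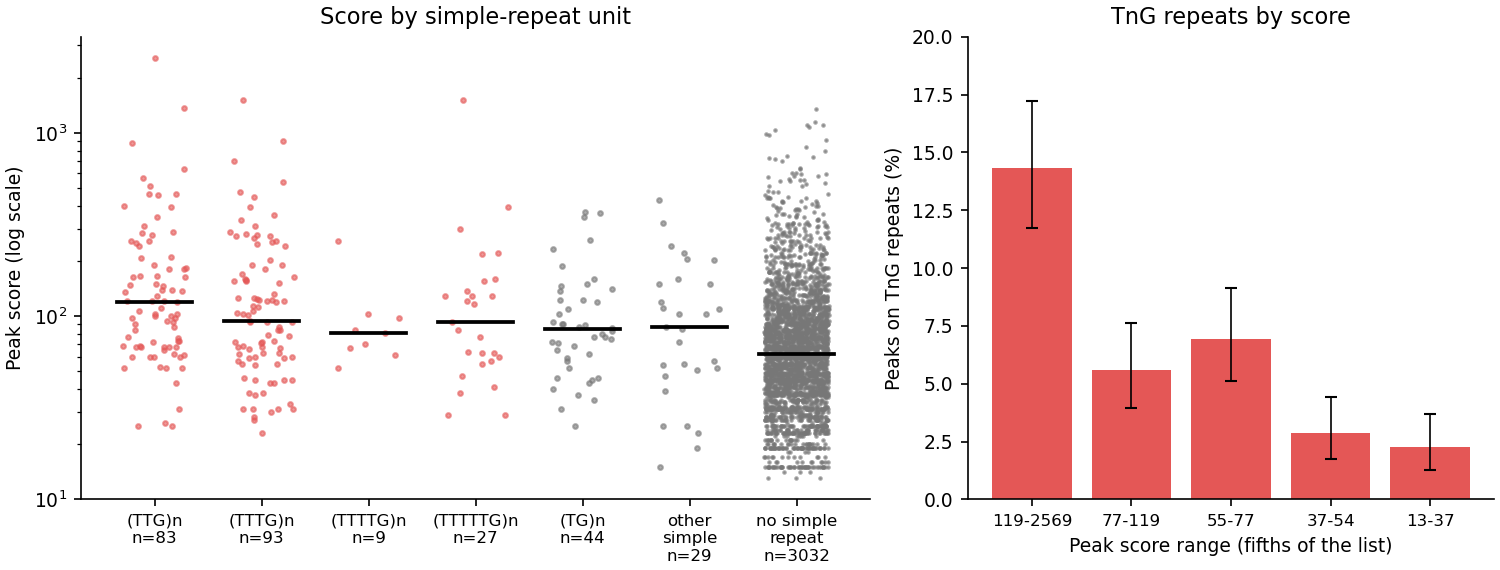
Left, score of each peak (log axis, points) by simple-repeat unit, with the median as a black line; TnG units are in red, other simple repeats and the 3032 peaks without one in grey. Right, share of peaks on TnG repeats (%) in 5 groups of 663 or 664 peaks by score, with exact 95% binomial intervals, at 14.3% in the highest group and 2.26% in the lowest.

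Regulators of adipogenesis had the highest share of members with a site among the 19 gene lists by nearest start site when all peaks were used. By nearest start site, 20 of 34 adipogenic regulators had a peak, against 9.03% of other protein-coding genes (odds ratio 14.4, 95% interval 6.90 to 30.8). Within 3 kb of the start site 7 of the 34 had one: Klf15 (score 141), Ep300 (64), Nfia (60), Tcf7l2 (52), Klf9 (46), Nfib (37) and Egr2 (25). The rank by promoter peaks depended on the window, since the clock genes had a higher share within 1 kb (3 of 24 against 4 of 34) and within 5 kb (5 of 24 against 7 of 34). Zbtb16, a zinc finger gene induced by glucocorticoids and singled out after its value was seen, had 5 peaks with scores up to 530 (in intron 2, chromosome 9, 48744877 to 48745541). Both counts passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 19 lists (adjusted p = 1.06e-11 for nearest start sites and 0.00010 within 3 kb). Against 10000 random lists of genes with territories of similar size, a permutation test, the first count also passed (5.73 expected, adjusted p = 0.0013). When peaks below the median score were left out, 1 regulator, Klf15, had a peak within 3 kb, and the promoter call was lost (odds ratio 3.03, Fisher's exact test, adjusted p = 0.68). By nearest start site 10 of 34 then had one (odds ratio 7.74), below the glucocorticoid-induced genes with 8 of 24 (9.27), and with gene bodies and 20 kb around them the odds ratio of the regulators was 7.18.

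Genes induced by glucocorticoids, a class that includes the dexamethasone of the induction medium, had a peak at 10 of 24 members by nearest start site (odds ratio 7.16, 2.84 to 17.4, Fisher's exact test, adjusted p = 0.00014). Among them were Klf15, Klf9 and Dusp1, a phosphatase gene with a promoter peak of score 47. This list shares 5 members with the adipogenic regulators, and without them, a test added after the data were seen, 7 of 19 had a peak (odds ratio 5.84, Fisher's exact p = 0.00097, not adjusted). Within 3 kb 3 of the 24 members had a peak, which did not pass after adjustment (odds ratio 6.75, exact test, adjusted p = 0.058), and within 5 kb 4 did, which passed (8.03, adjusted p = 0.016). Against territory-matched lists the nearest count passed (2.32 expected, permutation test, adjusted p = 0.0013).

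Markers of adipocyte progenitors and fibroblasts had a peak at 14 of 39 members by nearest start site (odds ratio 5.62, 2.70 to 11.3, Fisher's exact test, adjusted p = 4.14e-05, and 0.0013 against territory-matched lists). Promoter peaks lay at Dcn, a matrix proteoglycan gene (score 124), at the platelet-derived growth factor receptor gene Pdgfra (101), at the collagen cross-linking enzyme gene Lox (38) and at the surface marker gene Thy1 (24). These 4 of 39 did not pass Fisher's exact test within 3 kb (odds ratio 5.41, adjusted p = 0.054) and passed it within 1 kb (odds ratio 7.81, adjusted p = 0.023). Among markers of other cell types, by nearest start site, 0 of 20 macrophage markers, 2 of 20 endothelial markers (Pecam1 and Vwf), 1 of 15 smooth muscle and pericyte markers (Rgs5) and 3 of 15 mesothelial and epithelial markers (Esr1, Wt1 and Upk1b) had a peak, and none of these lists passed.

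The lists of TGF-beta and BMP, Wnt, and insulin and IGF signalling and of clock genes passed by nearest start site with smaller odds ratios. For TGF-beta and BMP signalling 13 of 41 members had a peak (odds ratio 4.66, exact test, adjusted p = 0.00021), with promoter peaks at Ski (score 69), Acvr2b (41) and Fst (25). Wnt signalling had 12 of 46 (odds ratio 3.54, exact test, adjusted p = 0.0025), with promoter peaks at Wnt5b (139), Wnt10b (67), Tcf7l2 (52) and Axin2 (28), and with Ror2. Insulin and IGF signalling had 9 of 36 (odds ratio 3.34, exact test, adjusted p = 0.012), with promoter peaks at Foxo3 (319), Igf1r (45) and Akt2 (20). Circadian clock genes had 7 of 24 (odds ratio 4.12, exact test, adjusted p = 0.012). Against territory-matched lists TGF-beta and BMP signalling passed (permutation test, adjusted p = 0.024), whereas Wnt signalling (0.091), insulin and IGF signalling (0.29) and the clock genes (0.078) did not. When peaks below the median score were left out, insulin and IGF signalling (odds ratio 2.98, exact test, adjusted p = 0.097) and the clock genes (2.64, adjusted p = 0.26) no longer passed, and with gene bodies and 20 kb around them Wnt signalling did not (2.23, adjusted p = 0.085). Within 3 kb the clock genes passed with 4 of 24, namely Csnk1d (63), Arntl (27), Rorb (21) and Nfil3 (15) (odds ratio 9.47, 2.34 to 28.4, exact test, adjusted p = 0.013), a call lost when peaks with a score under 30 were left out (odds ratio 2.47, adjusted p = 0.72). The TGF-beta and BMP, Wnt, and insulin and IGF lists did not pass the exact test within 3 kb, with 3 of 41 (adjusted p = 0.13), 4 of 46 (0.058) and 3 of 36 (0.10) members.

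Thermogenic and brown or beige fat genes did not stand out. By nearest start site 3 of 40 had a peak, against 9.11% of other genes (odds ratio 0.81, 0.16 to 2.56, Fisher's exact test, adjusted p = 1). These were Dio2, which activates thyroid hormone (score 93, 44.6 kb from the start site), Irf4 (52, at -27.4 kb) and Tmem26 (29, 157 kb). Within 3 kb 0 of 40 had one assigned to them (upper limit of the odds ratio 4.55). Peaks in that window that were closer to another gene's start site were not counted.

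The remaining lists did not pass with either assignment when all peaks were used. By nearest start site a peak was found at 7 of 38 lipid storage and lipolysis genes (odds ratio 2.26, exact test, adjusted p = 0.17), among them Elovl6 with a promoter peak of score 50. This list passed when peaks below the median score were left out (6 members, odds ratio 3.47, exact test, adjusted p = 0.039). A peak was found at 5 of 44 adrenergic and cAMP genes (1.28, exact test, adjusted p = 0.87), with Pde4b at 141, and at 7 of 34 forkhead genes (2.59, adjusted p = 0.074). It was found at 3 of 44 cell cycle genes (0.73, exact test, adjusted p = 1), 3 of 42 members of the respiratory chain list (0.77, adjusted p = 1), 2 of 52 ribosomal protein genes (0.40, adjusted p = 0.40) and 2 of 24 neuronal genes (0.91, adjusted p = 1). Promoter peaks of these lists included Mcm7 (95), Polg (40) and Atp5b (29).

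**Figure D3:**
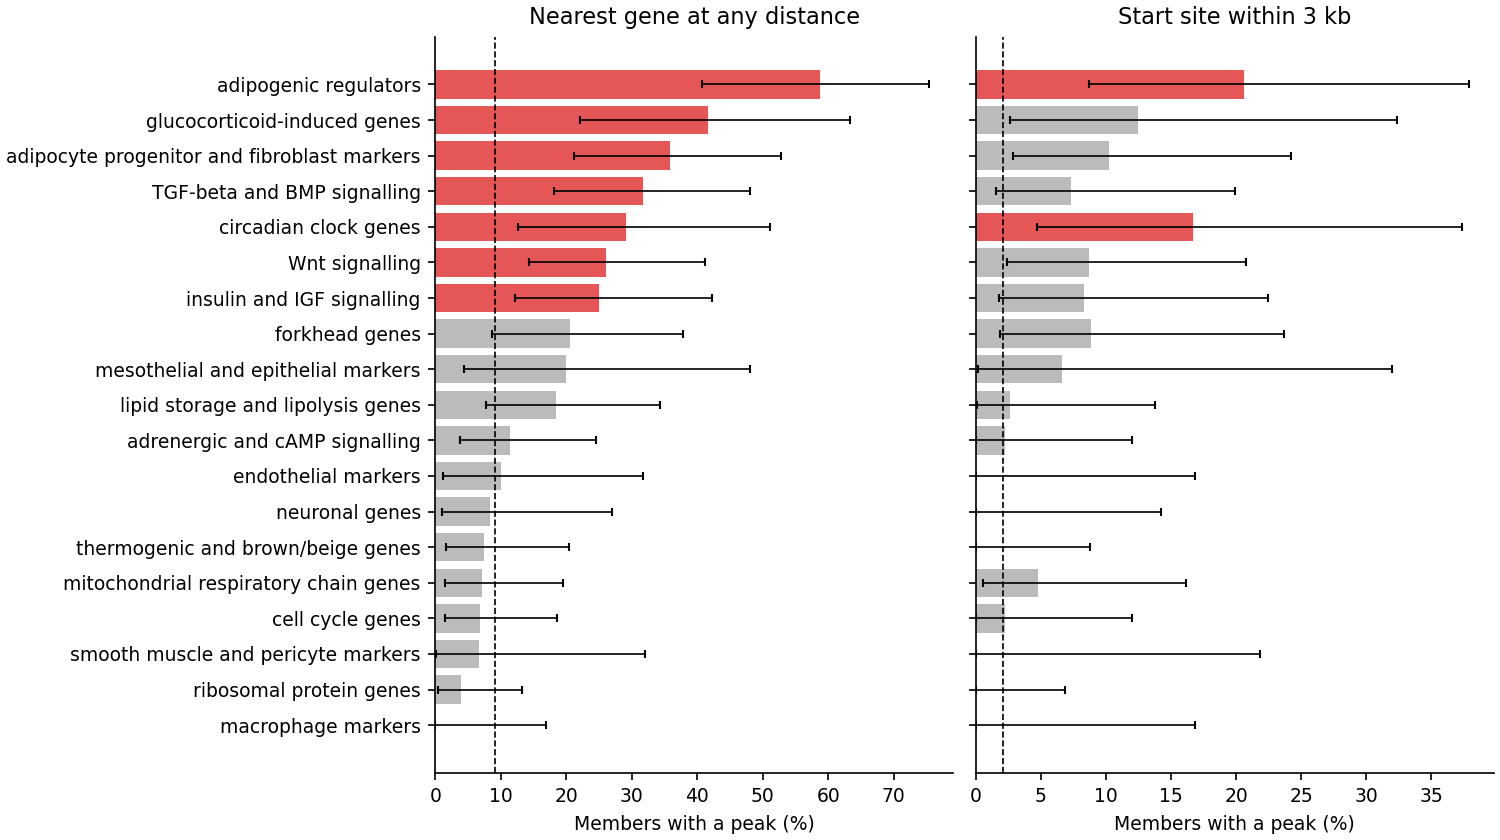
Share of the members of each of the 19 gene lists that had a peak (%), by nearest start site at any distance (left) and within 3 kb of the start site (right). Each peak counts only for its nearest gene. Lines are exact 95% binomial intervals, dashed lines mark all 21883 protein-coding genes (9.11% and 2.08%), and red bars are the 7 and 2 lists with an adjusted p under 0.05 in Fisher's exact test.

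Among the genes examined in every case, sites lay at other Foxp family genes and not near Foxp4 itself. Foxp1 was the nearest gene of 6 peaks, the highest with a score of 241 at -1.98 kb from the start site (chromosome 6, 99522676 to 99523261), and 4 lay in its intron 1. Foxp2 had 1 peak in its 5' UTR (score 38), and the peak closest to the Foxp4 gene lay 431 kb away. Pdgfra had a promoter peak at -107 bp (score 101, chromosome 5, 75151879 to 75152409) and another at -6.54 kb (77). Pparg, the central regulator of adipocyte differentiation, had 1 peak assigned to it, at -47.7 kb (28). Ebf2, a factor of brown and beige adipocytes, had 1 at -30.0 kb (52), and a peak in its intron 6 (42) was assigned to Gm6878. In the list tests Ebf2 was counted among the adipogenic regulators and not among the thermogenic and brown or beige fat genes. The early adipogenic factor gene Cebpb had none assigned, the closest lying 23.4 kb away (125). No peak was assigned to Ucp1, the uncoupling protein of thermogenic fat, or to Prdm16, with the closest 350 kb and 155 kb away. None was assigned to Ppargc1a either, although a peak with a score of 94, assigned to Mir6417, lay inside the gene as the reference table delimits it.

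**Figure D4:**
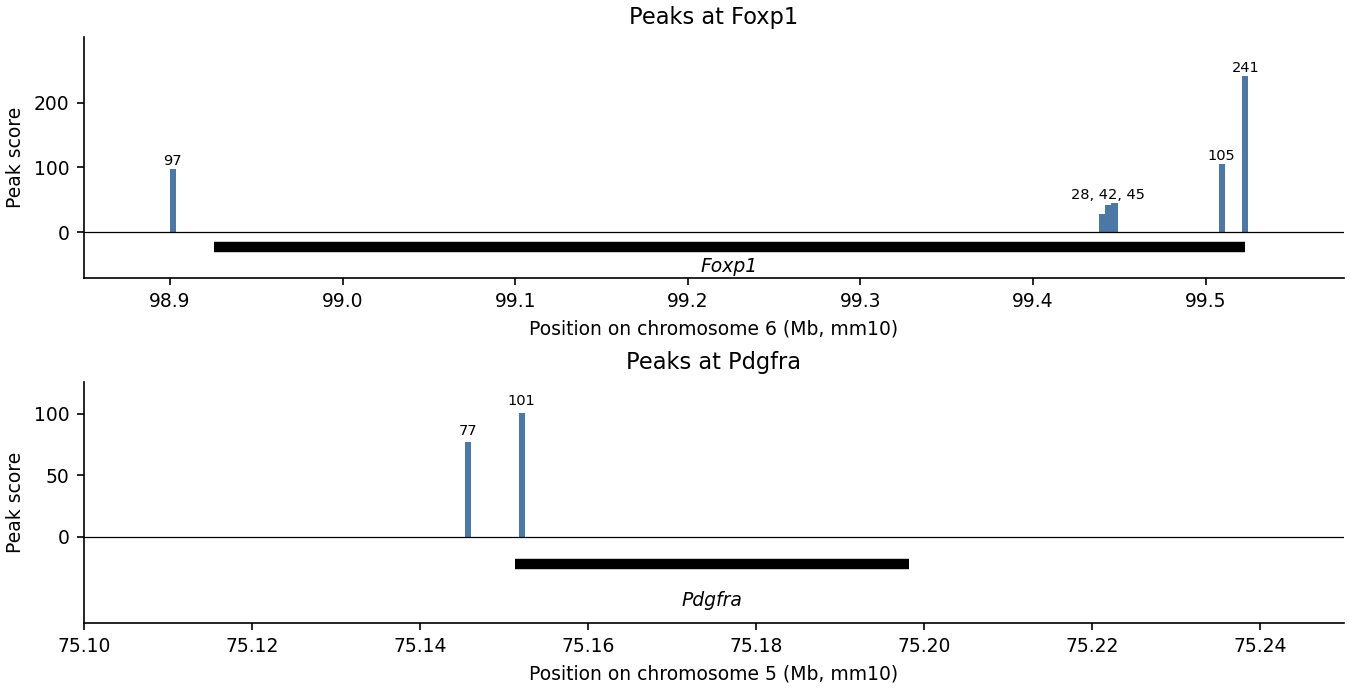
Peaks at Foxp1 (chromosome 6) and Pdgfra (chromosome 5), drawn at their midpoints (position in Mb, mm10) with the peak score as bar height and printed above; bars are wider than the peaks, and the black line is the gene. The highest Foxp1 peak (241) and the Pdgfra peak with a score of 101 lie at 1 end of their genes.

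Chromosome X held few sites. It carried 37 peaks, 0.217 per Mb of the span of annotated genes (exact Poisson interval 0.153 to 0.299), against 1.35 per Mb on the 19 autosomes, which ranged from 1.10 on chromosome 7 to 1.86 on chromosome 10. The ratio of X to autosomes was 0.160 (0.113 to 0.221), and per protein-coding gene it was 0.241 (0.170 to 0.334). None of the TnG peaks lay on X and 210 lay on autosomes (ratio 0, upper limit 0.251), and 8 X peaks lay within 3 kb of a start site (ratio 0.210, 0.0904 to 0.418). Chromosome Y carried 3 peaks (0.0333 per Mb, exact Poisson interval 0.00688 to 0.0975), of which 2 were TnG peaks. The median score of X peaks was 80 and that of autosomal peaks 64, a difference of 16 (-2 to 27) that did not pass a two-sided permutation test (p = 0.098). The densities per chromosome had been planned, whereas the ratios of X to autosomes and the comparison of scores were chosen after the counts were seen, and the number of reads on X was not analysed here.

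**Figure D5:**
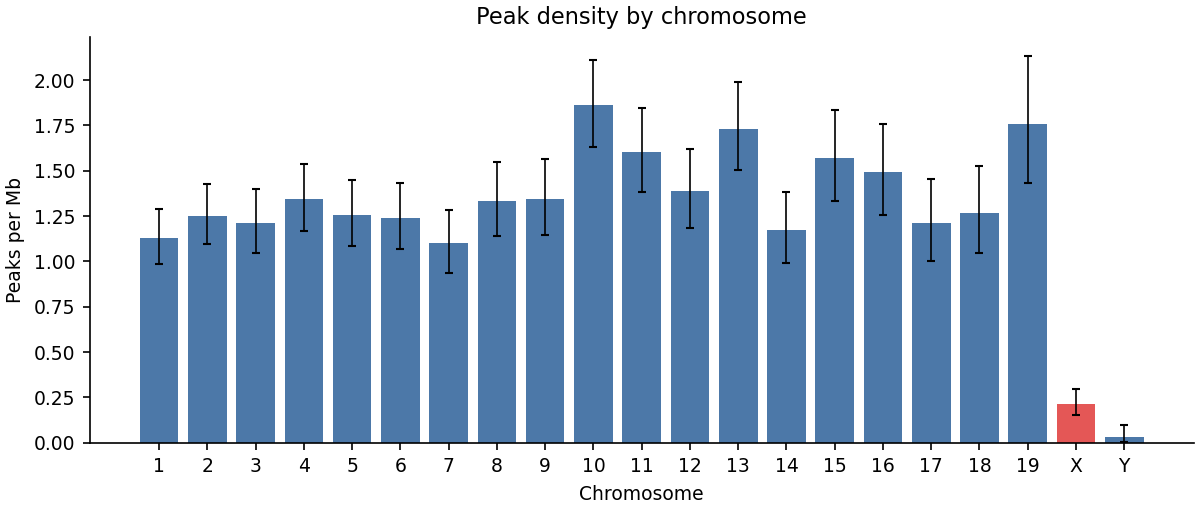
Peaks per Mb on each chromosome, over the span from the first to the last annotated gene, with exact 95% Poisson intervals. The autosomes lie between 1.10 and 1.86 per Mb and chromosome X, in red, at 0.217.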

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

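Alternatives for the repeat, ring, gene-end and X to autosome results, the gene-body assignment, the glucocorticoid list without shared members, the background of genes with curated coding transcripts and the list tests without simple-repeat peaks were chosen after the data were seen. No paired analysis was possible because each kind of library had 1 sample. The planned motif scan with its 5 alternatives and the chromosome length without assembly gaps were not run, since both need the genome sequence. Keeping peaks at or above the median score left 1663. The promoter share was 11.0% at 1 kb and 20.0% at 5 kb, which follows from the window, and stayed within its interval under the other alternatives. The number of lists with promoter peaks above chance went from 2 to 3 at 1 kb (progenitor markers gained) and at 5 kb (glucocorticoid-induced genes gained), to 1 at a score of at least 30 and to 0 at or above the median score, where fewer peaks were left. By nearest start site it was 6 or 7 under the 4 alternatives. The ratio of start-site peaks was 6.17 against the ring from 3 to 4 kb. The X to autosome ratio was 0.241 per protein-coding gene. The difference in score of TnG peaks was 39.5 against all other peaks, 38 without the 10 highest peaks, and between 8.5 and 15.5 against other simple repeats.

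For single lists 10 odds ratios changed side of 1, and the cause was not tested. Within 3 kb and at or above the median score they were 0 for the lipid, clock and respiratory chain lists. The mesothelial list had 0 at 1 kb, and the adrenergic and cell cycle lists 0.928 each at 5 kb. By nearest start site the adrenergic list had 0.849 within 100 kb and the endothelial list 0.970 at or above the median score. With gene bodies and 20 kb the cell cycle list had 1.03 and the smooth muscle list 2.01. Apart from the clock genes within 3 kb, these lists had not passed in the first place. Of the other results for single lists, 154 kept their side of the threshold, 5 lost it and 3 gained it. Without depth or input values, weak peaks near the caller's limit cannot be separated from background here.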

Other observations

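The count of neighbouring peaks, the genes with many peaks and the tests on chromosome X were chosen after the results were seen, and the repeat and start-site tests after the annotations of the highest peaks were seen but before their own values were. The tests without the 10 highest peaks and of other simple repeats against peaks with none were added last. Close pairs of peaks were more frequent than under random placement. In all, 205 pairs of neighbouring peaks lay within 10 kb of each other, against 44.8 ± 6.53 (SD) over 1000 random placements on the same chromosomes, in which the highest count was 65. The placements did not follow the excess of peaks at start sites and gene ends, so clustering beyond that excess was not tested. Genes nearest to many peaks were counted apart from these pairs, and without matching on gene territory. Marcks, which encodes a substrate of protein kinase C, was the nearest gene of 10 peaks over 418 kb, with scores up to 193. The closest of them lay 70773 bp from its start site. Adamts5, a matrix protease gene, had 9 peaks over 460 kb (up to 511), the closest at 19975 bp. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, had 9 over 582 kb (up to 109), the closest at 11194 bp. The microRNA gene Mir21a had 9 within 53.5 kb (chromosome 11, 86571381 to 86624877, up to 308). Rn4.5s, given the type ribosomal RNA in the annotation, had 9, of which 5 lay within 3 kb of its start site (up to 875). How reads with several alignments were treated is not given, and it could change the peaks at Rn4.5s. The interleukin 1 receptor gene Il1r1 had 5, of which 3 lay within 3 kb of the start site (up to 583).

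Peaks on TnG repeats had a median score of 101.5 against 62 for the other peaks. Width alone was argued against, since TnG peaks had the higher median in 4 of 4 quartiles of peak width (mean difference 74.6, permutation within quartiles, p = 1e-05, the smallest possible), and also without the 10 highest peaks, from which the group was formed (73.5, permutation p = 1e-05). The 73 peaks on other simple repeats also scored above peaks with no simple repeat, by 24 (9 to 41, permutation p = 0.00056), as did the 44 of them on (TG)n, by 22.5 (8.5 to 39, adjusted permutation p = 0.026). The interval for the remaining 29 included 0 (25, -8 to 59, permutation p = 0.019). It cannot be told apart whether any simple repeat gives such scores in full, because TnG peaks differed from other simple repeats by 15.5 with an interval from -4 to 39.5 (permutation p = 0.24). Nor can a part of the forkhead core TRTTTRY, which tandem (TTTG)n contains and the other TnG units lack, because (TTTG)n peaks differed from the other TnG peaks by -8 (-40.0 to 23, permutation p = 0.54). Tandem (TTTA)n, counted among the other simple repeats, also contains the core. Its 5 peaks had a median score of 149 (quartiles 120 to 205) and were not tested apart. A candidate explanation is binding of Foxp4 to TnG repeats, as is known for its relative Foxp3, and it stays untested beside the alignment of reads in repeats, since the input and the frequency of these repeats in the genome were not used here.

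Chromosome X had 0.160 times the peak density of the autosomes. A lower number of genes was argued against, since X had 3.83 peaks per 100 protein-coding genes (exact Poisson interval 2.70 to 5.28) and the lowest autosome had 7.88. A single copy of X, which could lower the signal of every X peak, cannot be told apart, because the difference in median score from autosomal peaks was 16 with an interval from -2 to 27, and peaks that fell below the caller's limit are not in the list. The sex of the mice and the input reads on X were not used here, and no biological explanation was tested.

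Peaks were 3.5 times as frequent within 1 kb of start sites as in the next 1 kb, without correction for the sequence available at each distance. Enrichment of open promoters regardless of the antibody could give this, and would favour genes active in most cells. The ribosomal protein and respiratory chain lists together had promoter peaks assigned to their members at an odds ratio of 1.02 (0.12 to 3.82, Fisher's exact p = 0.72, 2 of 94 members). The members with a peak were Polg and Atp5b, and Polg counts here by its place in the list, not as a subunit of the chain. With so few members this explanation cannot be told apart from binding chosen by Foxp4, and the input, which would bear on it, was not used here.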
